A study of Homo sapiens with 4 samples.

How the data were processed

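Total RNA of HUT78 cells, an established human line of cutaneous T-cell lymphoma, was measured on 4 single-sample Affymetrix whole-transcript arrays. Per the labels, 2 samples were treated with the compound CSH71 at 250 nM for 30 h and 2 were untreated, and the group and replicate number of each array were read from its title. The deposited values are linear intensities, 1 per probe set, and the submitters' processing notes name Affymetrix Expression Console as the software. Its version, the summarisation, the background correction and the normalization are not given in the sources used here. The intensities ran from 0 to 19331 over the 4 arrays. Array medians were 77.5 and 71.5 for untreated replicates 1 and 2, and 73.6 and 81.1 for CSH71 replicates 1 and 2. Values of exactly 0 numbered 252, 325, 375 and 149 in the same order. The values carry no detection call and no background level, so no gene is described here as present or absent, and the number of arrays limits the precision.

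Probe sets were named through the platform annotation and a RefSeq gene table of assembly GRCh38.p14, used for names alone: all 16098 entrez identifiers of probe sets with a symbol matched and 0 symbols changed. Of 53617 probe sets, 16098 had 1 symbol, 0 had several and 37519 had none in the annotation used. For the 779 genes with several probe sets, the one with the highest mean over the 4 arrays was used, which left 14884 genes. No genome build was named for the array design, so no coordinates are given. Among the genes named by rule, 5 have several probe sets, and these had opposite signs for BMF (-0.31 and 0.38) and LYZ (-0.06 and 0.23).

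Values were transformed to log2(intensity + 16) and not normalized again. A fold change on this scale understates the change of dim genes. The groups were compared with limma (version 3.58.1, R 4.3.3), which fitted 2 group means per gene, moderated the variances with default settings and adjusted 2-sided p-values by the Benjamini-Hochberg method over the 14884 genes. A gene was called at an adjusted p under 0.05. Sets of genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 sets that had at least 5 measured genes. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a set move one way on balance and makes no comparison with other genes. The 33 gene lists held 866 genes, of which 498 were measured under the symbol listed. The lists overlap: CD69, JUN, TNF, ATF3, SESN2, KLF6 and STAT4 each stand in at least 2 of them. The lists of death receptors and ligands, replication-dependent histones and mitochondrially encoded genes had 0 measured genes, and that of aryl hydrocarbon receptor targets had 3, so these 4 were not tested. Figures were drawn with matplotlib 3.10.9.

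The groups, the limma comparison, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The pseudocount was not: the design foresaw log2 values or a plain log2 transform, and the zeros in the linear table made an added constant necessary. The constant of 16 was chosen after the range of the values was seen, and it was fitted together with 1 and 64, which are given as alternatives. The naming rule took, in each direction, up to 12 called genes whose treated and untreated arrays did not overlap and which were brighter than the median gene in the higher group. Where fewer passed, the 5 next genes of that direction with the smallest p were added. It also took TNF, the p38 genes, up to 4 members of each list by smallest p, and up to 8 of the list ranked first.

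The alternatives were the replicate number as a block, quantile normalization, median centring of the arrays, removal of the dimmest 40% of genes, a variance prior that follows intensity, a robust prior, the mean of a gene's probe sets, all 53617 probe sets, and each array left out in turn. Other pseudocounts, quantile normalization with the degrees of freedom of the reported fit, a crossed pairing of the arrays, and lists without the called genes were added after the data had been seen. The procedure was tested on simulated data for this comparison, in 10 runs of 14884 genes with 200 changed. It called 14.2% of the genes changed 2-fold and 93.5% of those changed 4-fold. On average 5.7 of 113.5 calls per run were false. The data gave 7 calls, so these shares need not hold there. A list raised by 0.5 was called in 100% of the runs. The simulated genes were independent, had variances unrelated to intensity, and all members of that list were shifted alike. In the data, the estimated correlation of the lists called by camera ran from 0.07 to 0.41. The runs therefore do not show how camera performs on such lists.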

Results

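Gene expression was measured in HUT78 cells, a human T-cell line of the leukaemic form of cutaneous T-cell lymphoma, with and without the compound CSH71. The series describes CSH71 as directed at the lipid-binding domain of p38γ, the mitogen-activated protein kinase encoded by MAPK12. The question was which transcripts differed after 30 h at 250 nM, with TNF the gene that the design text singles out. There were 2 treated and 2 untreated arrays, whose median intensities lay between 71.5 and 81.1. Over all genes, the median absolute log2 difference was 0.22 between the untreated arrays and 0.19 between the treated arrays, against 0.17 to 0.24 for a treated and an untreated array. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

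CSH71-treated cells had higher RNA of JUN and FOSL2, members of the AP-1 transcription factor family, of CREM, a transcription factor of the cAMP response, and of CD69, an early surface marker of T-cell activation. DUSP4, a phosphatase that acts on mitogen-activated protein kinases, and IL2, a T-cell growth factor, were also higher. JUN rose from an intensity of 108 ± 26.8 to 828 ± 39.9 (mean ± SD, n = 2 per group), a log2 fold change of 2.79 ± 0.21 (SE). CREM rose by 2.47 ± 0.20 on the log2 scale, from 204 ± 39.7 to 1194 ± 95.4. CD69 was the brightest of these genes and rose by 2.37 ± 0.17, from 576 ± 50.5 to 3046 ± 43.3.

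DUSP4 rose from 18.7 ± 2.15 to 142 ± 19.8 (log2 fold change 2.18 ± 0.18), FOSL2 from 66.4 ± 0.233 to 316 ± 30.3 (2.01 ± 0.17) and IL2 from 37.1 ± 7.10 to 188 ± 18.9 (1.94 ± 0.19). The single gene called lower was SCARNA3, a small Cajal body RNA, which fell from 918 ± 89.2 to 214 ± 33.9 (log2 fold change -2.03 ± 0.19). For each of these 7 genes both treated arrays lay on the same side of both untreated arrays. The limma adjusted p was 0.0224 for JUN and CD69, 0.0245 for CREM, DUSP4 and FOSL2, and 0.0383 for IL2 and SCARNA3.

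**Figure D1:**
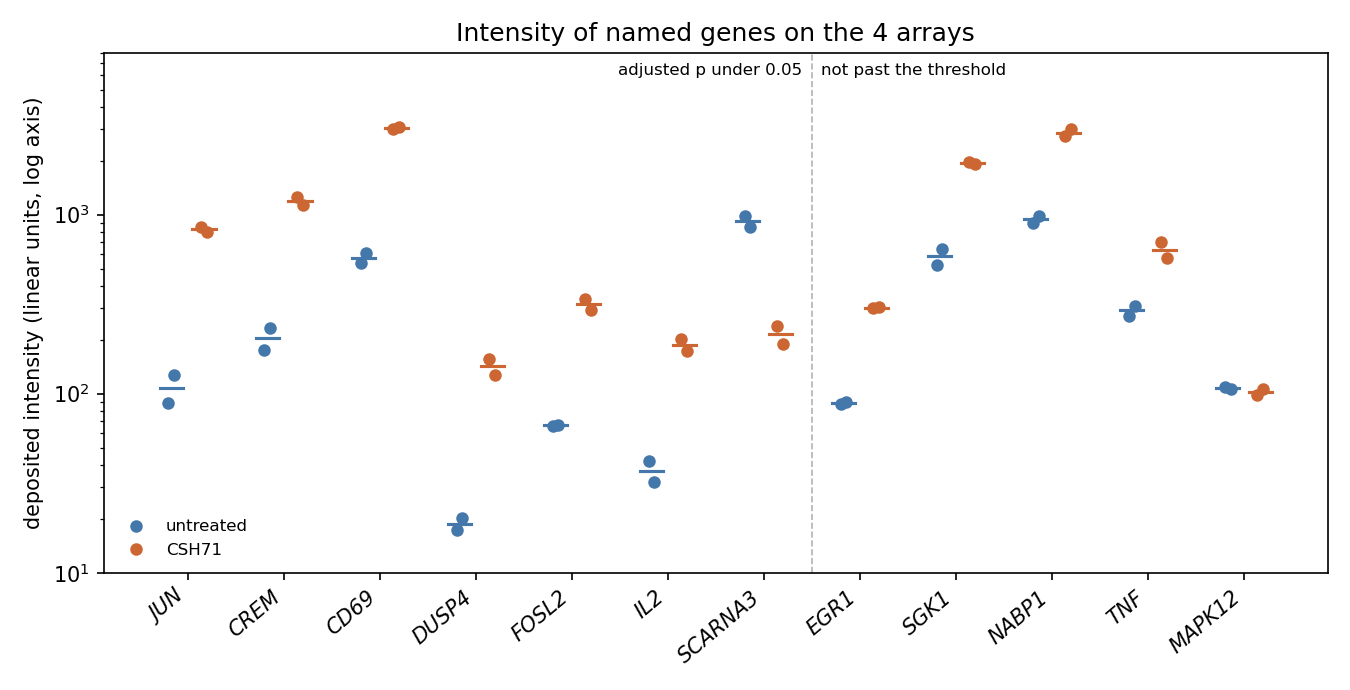
Deposited intensity (linear units, logarithmic axis) of 12 genes on the untreated (blue) and CSH71 (orange) arrays, where each point is an array and each bar a group mean. Genes left of the dashed line had a limma adjusted p under 0.05, among them CD69 at 576 untreated and 3046 treated, and those right of it did not.

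Those 7 genes, 6 higher and 1 lower, were all that passed among 14884, and all 7 differed at least 2-fold. At an unadjusted p under 0.05 there were 760 genes, 476 higher and 284 lower, where 744 would arise by chance. The share of genes whose groups did not overlap was 31.6%, where chance gives 33.3% for 2 against 2. Regardless of p, 35 genes differed at least 2-fold, 30 higher and 5 lower.

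Of the further genes named by rule, EGR1, SGK1 and NABP1 lay close to the threshold without passing it, and the others lay far from it. EGR1, an immediate early transcription factor, had a log2 fold change of 1.60 ± 0.16 (adjusted p = 0.0516), and its other probe set gave 0.07. SGK1, a serum- and glucocorticoid-regulated kinase, had 1.70 ± 0.18 and NABP1, a single-stranded DNA-binding protein, had 1.59 ± 0.17 (both adjusted p = 0.0559). SIK1, a salt-inducible kinase, had 1.33 ± 0.18 (0.232) and the deubiquitinase gene JOSD1 had 1.22 ± 0.18 (0.275). In the other direction, the genes with the smallest p were LRRN3 at -0.94 ± 0.17 (adjusted p = 0.515), HHIP, which encodes a hedgehog-binding protein, at -0.92 ± 0.17 (0.640), CREB3L3 at -1.14 ± 0.22 (0.655), the interferon-induced gene RSAD2 at -0.93 ± 0.19 (0.742) and SPSB1 at -0.85 ± 0.18 (0.742).

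Over all alternatives in which they were tested, the log2 fold changes of the 7 called genes ran from 2.39 to 3.01 for JUN, 2.24 to 2.65 for CREM, 2.28 to 2.46 for CD69, 1.31 to 2.85 for DUSP4, 1.54 to 2.23 for FOSL2, 1.32 to 2.32 for IL2 and -2.18 to -1.82 for SCARNA3. The number of calls varied: limma called 0 genes without untreated replicate 1 (794 at an unadjusted p under 0.05) and 0 without untreated replicate 2 (609), but 29 without CSH71 replicate 1 and 20 without CSH71 replicate 2, with the 7 genes among both. It called 0 after quantile normalization (927 at an unadjusted p under 0.05), 0 with a pseudocount of 1 (768), 33 with a pseudocount of 64, and 43 after median centring, 32 higher and 11 lower against 6 and 1 without it.

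**Figure D2:**
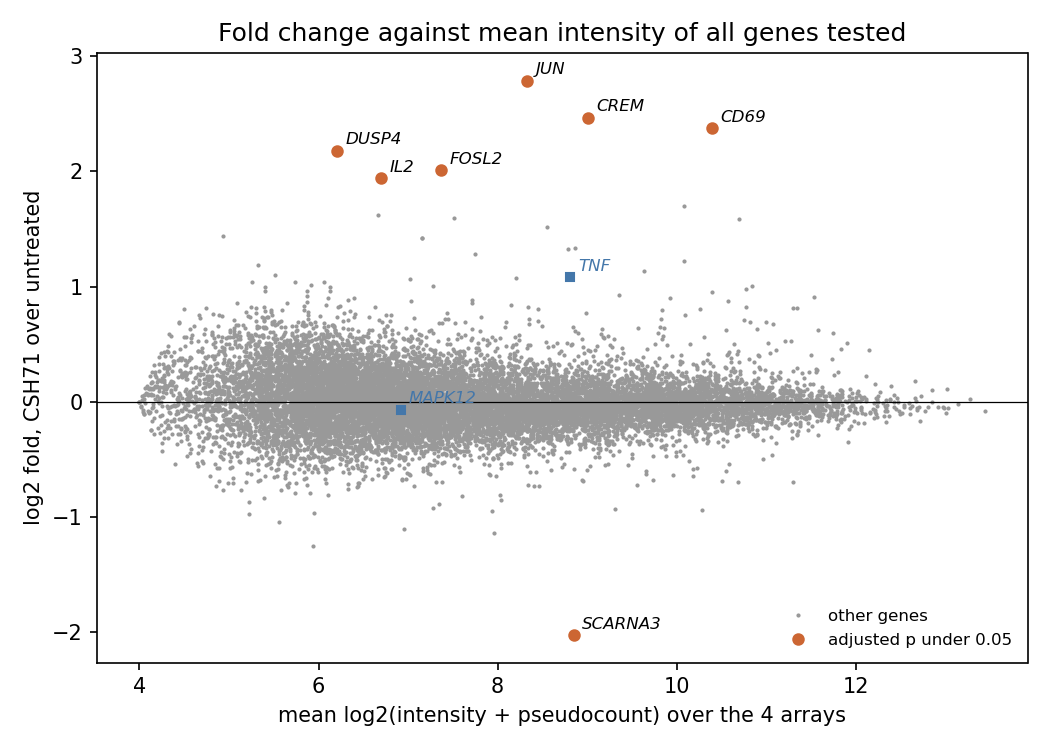
Log2 fold change of CSH71 over untreated cells (vertical axis) against the mean log2 intensity with the pseudocount over the 4 arrays (horizontal axis), 1 point per gene for 14884 genes. The 7 genes with a limma adjusted p under 0.05 are orange and named, from SCARNA3 at -2.03 to JUN at 2.79, and blue squares mark TNF at 1.08 and MAPK12 at -0.07.

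TNF, the inflammatory cytokine named in the design text, had an intensity of 292 ± 26.2 in untreated and 637 ± 95.6 in CSH71-treated cells. Its log2 fold change was 1.08 ± 0.19, with a 95% interval of 0.63 to 1.53, and it was higher on both treated arrays than on both untreated ones. It did not pass the limma threshold (adjusted p = 0.515). Its 8 probe sets gave 1.08 to 1.18. The value crossed the threshold in 4 of 14 alternatives, among them a variance prior that follows intensity, with adjusted p-values from 8.02e-07 to 1 over all alternatives. With the replicate block, median centring or that prior, limma's prior degrees of freedom were infinite, so a gene's own spread did not enter its p-value. Those crossings therefore rest on a variance assumed for TNF, not on its replicates. The study picked TNF on these samples, so its direction here is not independent evidence.

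MAPK12 itself had an intensity of 108 ± 1.45 in untreated and 102 ± 5.99 in treated cells. Its log2 fold change was -0.07 ± 0.17 with a 95% interval of -0.46 to 0.33 (limma adjusted p = 0.999), so a 2-fold change of the measured signal lay outside the interval. MAPK12 was dimmer than the median gene (mean log2 value 6.92 against 7.26) and no background level is given. The interval therefore does not bound the change of its RNA. MAPK11 was at -0.10 ± 0.20 and MAPK13 at -0.09 ± 0.18, each with overlapping groups. Because CSH71 is described as acting on the protein, the RNA level is no check of the labels. MAPK14 was not analysed here.

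The gene lists describe which processes these genes belong to. Immediate early genes, which respond within minutes to growth and stress signals, were higher as a group (limma camera adjusted p = 2.06e-08; 0.921 as an adjusted p with an estimated correlation). Of 21 measured, JUN and FOSL2 rose, 0 fell and 19 did not pass; adjusted over the list alone, 6 passed upwards, which added EGR1, KLF6 (0.87 ± 0.18), JUND (0.82 ± 0.17) and ATF3 (0.90 ± 0.20). DUSP1 at 0.53 and IER2 at 0.52 passed neither adjustment. The mean log2 fold change of the list was 0.50 and its median 0.18. Of its members 16 had a positive and 5 a negative fold change. Among the negative were FOS (-0.10 ± 0.21), FOSB (-0.07 ± 0.27) and MYC (-0.11 ± 0.16).

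Targets of TNF and NF-κB were also higher as a group (camera adjusted p = 5.33e-05; 0.921 as an adjusted p with an estimated correlation). Of 30 measured, CD69 alone rose, 0 fell and 29 did not pass; adjusted over the list alone, 8 passed upwards. Examples are KLF6, and TRAF1, an adaptor of TNF receptors, at 675 ± 57.6 and 1182 ± 6.26 in untreated and treated cells (log2 fold change 0.80 ± 0.17). In this list 22 members had a positive fold change and 8 a negative one, with a median of 0.12. The study had looked at TNF and its downstream pathway on these arrays, so neither count is independent evidence of direction. Components of TNF receptor signalling gave a camera adjusted p of 0.367, which passed upwards with the replicate block (0.0237), median centring (0.0236), an intensity trend in the prior (0.00145) or without CSH71 replicate 2 (0.0245), from 0.00145 to 0.921 over all alternatives. Of 24 measured, JUN rose and 23 did not pass, and JUN and TNF passed when adjusted over the list alone, while MLKL, the executor of necroptosis, was at -0.49 ± 0.17. That list was likewise not independent of the study's choice.

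The p38 pathway list includes the p38 kinases and phosphatases of mitogen-activated protein kinases in general. It was higher as a group (camera adjusted p = 0.00557, and 0.921 as an adjusted p with an estimated correlation). Of 25 measured, DUSP4 rose and 24 did not pass; adjusted over the list alone, 3 passed upwards, and all 3 were dual-specificity phosphatases that dephosphorylate mitogen-activated protein kinases: DUSP4, DUSP6 (0.98 ± 0.17) and DUSP8 (0.88 ± 0.18). The median of the list was 0.02 against a mean of 0.24, with 13 members positive and 12 negative. MAPK11 (-0.10), MAPK12 (-0.07) and MAPK13 (-0.09) did not rise. The group call thus rested on a few members, not on the pathway as a whole. MEF2D, a transcription factor phosphorylated by p38, was at 0.53 ± 0.17.

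The list for ATF4 and the integrated stress response was higher as a group (camera adjusted p = 0.00372; 0.921 as an adjusted p with an estimated correlation). Of 24 measured, 0 passed over all genes (760 of all genes tested by limma had an unadjusted p under 0.05) and 2 passed when adjusted over the list alone, ATF3 and SESN2 (0.77 ± 0.18). ATF4 itself was at 3092 ± 146 untreated and 4245 ± 157 treated, a log2 fold change of 0.46 ± 0.17, and 18 members had a positive and 6 a negative fold change. Interferon response genes were lower as a group (camera adjusted p = 0.0135; 0.921 as an adjusted p with an estimated correlation). Of 24 measured, 0 passed over all genes and 1, RSAD2, passed downwards when adjusted over the list alone. The list's median was -0.17, with IFIT2 at -0.55 ± 0.20 and HERC6 at -0.43 ± 0.18 but IFIT3 at 0.43 ± 0.19.

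Under fry, the immediate early genes alone passed among the 5 lists (adjusted p = 0.0118, the others from 0.410 to 0.530), and with an estimated correlation 0 lists passed. Leaving out untreated replicate 1 ended the calls of the p38 list (adjusted p = 0.223) and the ATF4 list (0.118), leaving out CSH71 replicate 1 ended those of both (0.132 each) and of the interferon list (0.0733), and the interferon call also ended without untreated replicate 2 (0.264) or CSH71 replicate 2 (0.109).

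**Figure D3:**
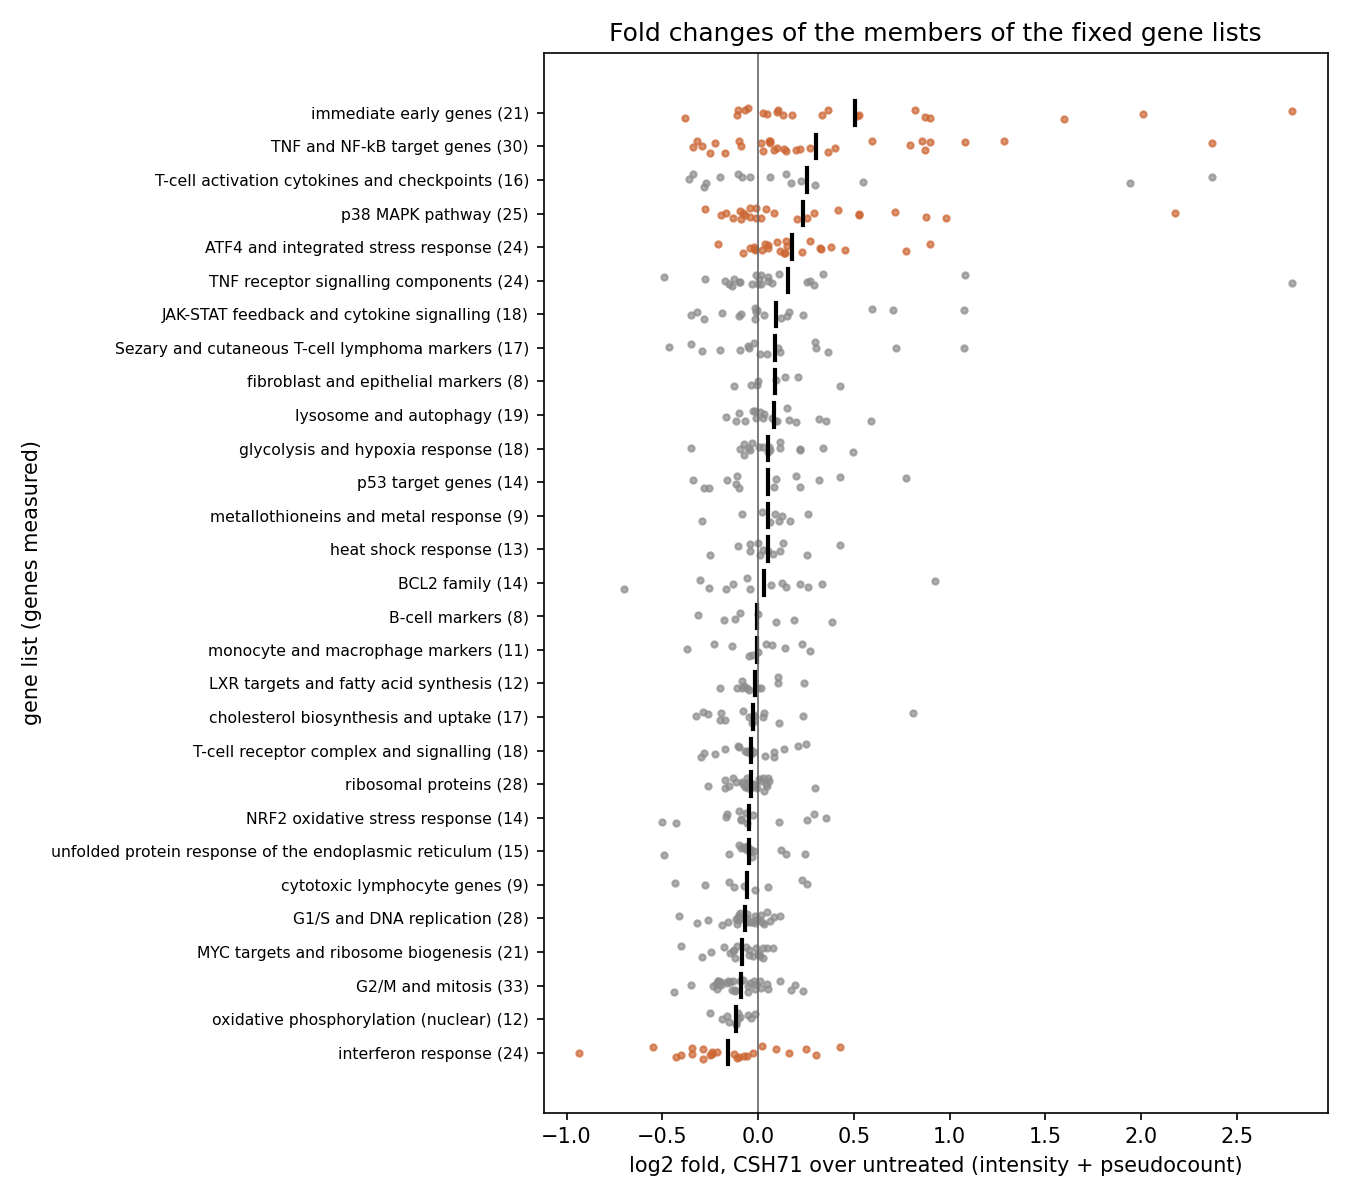
Log2 fold change of CSH71 over untreated cells (horizontal axis) of each measured member of the 29 tested gene lists (vertical axis, number of genes in parentheses), where points are genes, black bars are list means and orange marks the 5 lists with a camera adjusted p under 0.05. The list means run from 0.50 for immediate early genes to -0.16 for interferon response genes.

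Among T-cell genes, the list of activation cytokines and checkpoints held 2 of the called genes, CD69 and IL2, which rose and also passed when adjusted over the list alone, while the other 14 of 16 measured did not pass. As a group it missed the threshold (camera adjusted p = 0.282) but passed upwards with the replicate block (0.000862), median centring (0.000855) or an intensity trend in the prior (2.45e-06), and turned downwards when the called genes were left out (0.723), from 2.45e-06 to 0.921 over all alternatives. Its median was 0.01, with 8 members positive and 8 negative, and those that did not pass include IL21, a cytokine of helper T cells, at 0.55 ± 0.19 and IL10, an inhibitory cytokine, at -0.36 ± 0.18. In the lists of JAK-STAT signalling (18 measured, adjusted p = 0.441) and of Sézary and cutaneous lymphoma markers (17 measured, 0.561), 0 genes passed over all genes and STAT4 passed upwards in each when adjusted over the list alone, at 188 ± 17.1 untreated and 415 ± 68.3 treated. The chemokine receptor CCR7 was at -0.47 ± 0.17, the cytokine receptor IL7R at 0.71 ± 0.18 and the chromatin organiser SATB1 at 0.72 ± 0.18. The T-cell receptor complex (18 measured, adjusted p = 0.568) and cytotoxic genes (9 measured, 0.594) had 0 genes past the threshold by either adjustment, with list medians of -0.04 and -0.07 and examples in CD247, the zeta chain of the receptor, at -0.30 ± 0.18 and PRF1, perforin, at -0.28 ± 0.17.

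Cell-cycle and growth lists had small negative medians and missed the threshold as reported. Genes of mitosis had a median of -0.12 over 33 measured (camera adjusted p = 0.0746), with KIF20A at -0.44 ± 0.17 and CENPA at -0.35 ± 0.17, and 25 of the 33 had a negative fold change. Genes of DNA replication had a median of -0.06 over 28 (0.264), with E2F8 at -0.41 ± 0.18. MYC targets had -0.05 over 21 (0.240) and ribosomal proteins -0.04 over 28 (0.561). In each of these 4 lists 0 genes passed over all genes or adjusted over the list alone, with 760 of all genes at an unadjusted limma p under 0.05. With an intensity trend in the prior all 4 passed downwards: mitosis (adjusted p = 0.000147, from 0.000147 to 0.921 over all alternatives, and 0.0204 with a pseudocount of 64), replication (0.0347, to 0.988), MYC targets (0.0107, to 0.921) and ribosomal proteins (0.0433, to 0.921). In the BCL2 family (14 measured, adjusted p = 0.804) 0 genes passed over all genes, and adjusted over the list alone PMAIP1, which encodes the pro-apoptotic protein NOXA, passed upwards at 0.92 ± 0.19 and BCL2L11, which encodes the pro-apoptotic protein BIM, passed downwards at -0.70 ± 0.17. Among p53 targets (14 measured, adjusted p = 0.568), SESN2 passed when adjusted over the list alone.

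Stress and metabolic lists other than ATF4 did not pass as reported. The unfolded protein response (15 measured, median -0.06, camera adjusted p = 0.568), NRF2 targets (14, -0.07, 0.568), heat shock genes (13, 0.03, 0.594) and metallothioneins (9, 0.09, 0.561) had 0 genes past the threshold by either adjustment, and ERN1, a sensor of unfolded proteins, was at -0.49 ± 0.19 and HMOX1, haem oxygenase, at -0.50 ± 0.17. Cholesterol synthesis (17, -0.03, 0.568) held STARD4, a sterol carrier, which passed upwards when adjusted over the list alone at 0.81 ± 0.17. LXR targets (12, -0.05, 0.804), glycolysis and hypoxia (18, 0.04, 0.561), oxidative phosphorylation (12, -0.11, 0.197) and lysosome and autophagy (19, 0.03, 0.319) had 0 genes past the threshold by either adjustment, and oxidative phosphorylation alone of these passed with an intensity trend in the prior, downwards (0.00465, from 0.00465 to 0.921 over all alternatives). VEGFA, an angiogenic factor, was at 0.49 ± 0.18 and MAP1LC3B, an autophagosome protein, at 0.59 ± 0.17. The 3 measured targets of the aryl hydrocarbon receptor list, which was not tested, were TIPARP at -0.32, ARNT at -0.10 and AHR at 0.02, where AHR turned to -0.03 after median centring. The mean and median differed in sign for p53 targets (0.05 and -0.01), JAK-STAT genes (0.09 and -0.01) and monocyte markers (-0.01 and 0.00), where camera followed the mean.

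Markers of other cell types were not called. B-cell (8 measured, median -0.05, camera adjusted p = 0.914), monocyte (11, 0.00, 0.914) and fibroblast and epithelial markers (8, 0.05, 0.520) had 0 genes past the threshold by either adjustment. LYZ, lysozyme, was at 27.7 untreated and 36.0 treated, S100A9 at 118 and 97.7, and CD14 at 77.5 and 81.2. EPCAM, an epithelial adhesion molecule, was bright in both groups, at 2062 and 2056.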

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

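The tests in this part on the 6 higher genes and on SCARNA3 were chosen only after those results had been seen. Signal outside the named genes drew attention first: among the 37519 probe sets without a symbol, 30 differed at least 2-fold with an unadjusted p under 0.001, 25 higher and 5 lower, where 17 named genes' probe sets did so when all 53617 probe sets were fitted with limma. None of the 53617 had an adjusted p under 0.05 in that fit (smallest 0.161, with 2367 at an unadjusted p under 0.05). The probe set with the smallest p, 17087517, had a mean intensity of 42.8 ± 7.09 (SD, n = 2) in untreated and 375 ± 51.7 in treated cells. Probe set 16888979 had 512 ± 28.9 and 1883 ± 8.82. Of those lower, probe set 16652999 had 81.1 ± 0.368 and 11.04 ± 0.474. Their genes are unnamed here.

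JUN, CREM, CD69, DUSP4, FOSL2 and IL2 were higher with CSH71. Array medians already lay between 71.5 and 81.1, so quantile normalization had little to move and could hardly have removed such folds. Brightness differences between whole arrays were thus too small to be the whole cause, and those confined to some probe sets were not tested. After quantile normalization, the smallest of the 6 log2 fold changes, that of IL2, was 1.91 ± 0.16 (SE), against 1.94 ± 0.19 before. The 6 calls ended there (adjusted p = 0.112 for each, with values up to 0.448 over all alternatives of the 6) although the folds barely moved, because limma's prior degrees of freedom fell from 4.92 to 3.06: with the degrees of freedom of the reported fit, the quantile-normalized values gave 11 calls, all 7 genes among them. Cells of a non-T type in the treated cultures are argued against only as far as the measured markers reach. By type, the median log2 fold change was -0.05 for 8 B-cell, 0.00 for 11 monocyte and 0.05 for 8 fibroblast and epithelial markers. The median over all 27 was 0.000301 (SD 0.19), which alone could hide a rise of 1 type. S100A9 was at 118 untreated and 97.7 treated and LYZ at 27.7 and 36.0. Several markers were dim in both groups, LYZ among them, so a small admixture is not excluded. These markers say nothing of other T cells. Handling or stress of the treated cultures other than the compound's action cannot be told apart from the compound, because no vehicle control is among the samples analysed, and heat shock genes had a median log2 fold change of 0.026. A response to CSH71 stays open as a hypothesis.

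SCARNA3 was lower with CSH71. A lower recovery of small RNAs is argued against, because the 22 other small Cajal body RNAs had a median log2 fold change of -0.075 (SD 0.17), from -0.36 to 0.21. After quantile normalization the log2 fold change of SCARNA3 was -2.03 ± 0.19, against -2.03 ± 0.19 before, although that call ended too (limma adjusted p = 0.152). The array medians differed little, so this speaks only against brightness differences between whole arrays. A response of this RNA to CSH71 stays open as a hypothesis, and a batch or handling difference between the groups was not tested.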

How the results depend on the processing

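The pseudocounts of 1 and 64, quantile normalization with the reported degrees of freedom, the crossed pairing and the lists without called genes were chosen only after the data had been seen. Against 7 called genes (6 higher, 1 lower, all at least 2-fold), limma called 28 with the replicate block (24 and 4, all 28 at least 2-fold), 43 after median centring (32 and 11, 31 at least 2-fold), 11 without dim genes (10 and 1), 143 with an intensity trend in the prior (99 and 44, 33 at least 2-fold) and 33 with a pseudocount of 64 (29 and 4, 15 at least 2-fold). It called 0 after quantile normalization (927 at an unadjusted p under 0.05), with a pseudocount of 1 (768) and over all probe sets (2367), and 7 with a robust prior or probe-set means. The 7 genes were among the calls with the block, median centring, the trend and a pseudocount of 64, and 5 of them remained without dim genes, where DUSP4 and IL2 were not tested. Leaving out an array gave 0 to 29 calls (0 to 29 at least 2-fold, 0 to 27 higher, 0 to 8 lower): 0 without untreated replicate 1 (794 at an unadjusted p under 0.05) or 2 (609), 29 without CSH71 replicate 1 and 20 without CSH71 replicate 2, where the lone array is assumed to vary like the other group. Limma's prior degrees of freedom were 2.65 with a pseudocount of 1, 3.06 after quantile normalization, 4.55 without an untreated array, 4.92 as reported, 12.04 with a pseudocount of 64, 19.8 without a treated array and infinite with the block, centring or trend. In these settings 0 calls came at 4.55 or less and 20 or more at 12.04 or more. Quantile-normalized values set against the reported degrees of freedom gave 11 calls (10 higher, 1 lower, all 11 at least 2-fold), the 7 genes among them, so the lower degrees of freedom ended the calls there; for the other settings the cause was not tested. Infinite prior degrees of freedom mean that a gene's own spread does not enter its p-value. The block and centring then gave all genes the same variance, although residual variance in the reported fit fell from 0.0657 in the dimmest 10% to 0.00558 in the brightest 10%. Fewer dim genes and the additional probe sets also change the number of tests. Nothing in the labels pairs arrays of one number, and deviations of same-numbered arrays correlated at -0.29 over genes. Replicates differed with intensity, in opposite ways in the 2 groups. In intensity decile 4 the median log2 difference of replicate 1 minus 2 was 0.13 untreated and -0.10 treated. In decile 8 it was -0.19 and 0.12. By median absolute log2 difference, untreated 1 with CSH71 2 (0.175) and untreated 2 with CSH71 1 (0.183) were closer than replicates of a group (0.216 and 0.194). Crossing the pairs gave 0 calls, 0 at least 2-fold, with 1291 genes at an unadjusted p under 0.05. For TNF, adjusted p-values over the alternatives ran from 8.02e-07 to 1, and 4 lay under the threshold: the block (log2 fold change 1.08, adjusted p = 0.0425), median centring (1.04, 0.0164), the trend (1.08, 8.02e-07) and a pseudocount of 64 (0.97, 0.0108). MAPK12 kept its sign and its side of the threshold in all 14 alternatives, from -0.12 to -0.02.

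Lists past the threshold numbered 5, 12 with the trend, 0 with an estimated correlation, 1 under fry, 2 to 5 when an array was left out (3 without untreated replicate 1, 2 without CSH71 replicate 1), and 5 without the called genes. With an estimated correlation all 5 had an adjusted p of 0.921, and under fry the TNF target and ATF4 lists had 0.410, the p38 list 0.529 and the interferon list 0.530. When an array was left out, adjusted p ran from 0.000403 to 0.223 for the p38 list, 0.00382 to 0.132 for ATF4 and 0.0118 to 0.264 for interferon. Robust prior, all probe sets, crossed pairing and quantile normalization with the reported degrees of freedom were not run for lists.

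Directions reversed for BMF with probe-set means (0.035) and AHR after median centring (-0.029), and, as camera adjusted p, for BCL2 (0.863) and Sézary markers (0.793) with the trend, NRF2 (0.677) and LXR (0.992) without dim genes, LXR after quantile normalization (0.997), and T-cell activation without called genes (0.723); except for BMF, whose probe sets disagree, and T-cell activation, which lost CD69 and IL2, the cause was not tested. With an array left out, reversing log2 fold changes ran from -0.012 to 0.31 for ATF6, -0.37 to 0.071 for SDF2L1, -0.65 to 0.063 for MT1B, -0.033 to 0.29 for MT1X, -0.25 to 0.054 for ARNT, -0.033 to 0.064 for AHR, -0.27 to 0.056 for LPCAT3, -0.42 to 0.038 for COX8A, -0.36 to 0.0065 for PAX5, -0.038 to 0.49 for LYZ, -0.49 to 0.24 for KRT19, -0.31 to 0.12 for MAPK11 and -0.24 to 0.061 for MAPK13. Adjusted p of reversing lists ran from 0.268 to 0.881 for p53, 0.568 to 0.918 for BCL2, 0.198 to 0.986 for unfolded proteins, 0.289 to 0.921 for NRF2, 0.188 to 0.919 for cholesterol, 0.1995 to 0.659 for LXR, 0.194 to 0.907 for glycolysis, 0.365 to 0.987 for the T-cell receptor, 0.565 to 0.717 for B cells and 0.125 to 0.711 for monocytes; none of these genes or lists was called. Named genes gave 1742 such comparisons, of which 1622 kept direction and side, and uncalled lists 355, of which 321 did and 13 passed: T-cell activation with the block (0.000862), median centring (0.000855) or the trend (2.45e-06), TNF receptor signalling with these (0.0237, 0.0236, 0.00145) or without CSH71 replicate 2 (0.0245), mitosis with the trend (0.000147) or a pseudocount of 64 (0.0204), and, with the trend, replication (0.0347), MYC targets (0.0107), ribosomal proteins (0.0433) and oxidative phosphorylation (0.00465). The cause was not tested. Residual variance fell from 0.0657 in the dimmest 10% to 0.00558 in the brightest 10% of genes, so dim genes are measured least precisely.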

Other observations

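The genes RGS16, RGS1, MIR21, CEMIP2 and PTGS2 were chosen after their values were seen; the tests of signalling routes were planned before theirs, but the demands on scatter and on the called genes by which they are read were set after. RGS16 and RGS1, which shorten signalling through G-protein-coupled receptors, had log2 fold changes of 1.13 ± 0.18 (SE, n = 2 per group) and 0.95 ± 0.17, with limma adjusted p = 0.376 and 0.515. The microRNA gene MIR21 was at 1.51 ± 0.23 (0.334). CEMIP2, a cell-surface hyaluronidase gene, was at 1.32 ± 0.20 (0.305), and PTGS2, which encodes the inducible prostaglandin synthase COX-2, at 1.28 ± 0.31 (0.927).

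JUN, FOSL2, CD69 and IL2 are induced by several routes, so further genes of these routes that had not been looked at were tested. If raised ERK output were the source, its other output and feedback genes may be expected to rise, and the 10 measured had a median log2 fold change of 0.019 (SD 0.20, camera adjusted p = 0.965). For raised CREB target expression, which CREM might reflect, the 5 measured genes had a median of -0.064 (SD 0.47, camera adjusted p = 0.971). PER1 was at 0.51 and GEM at -0.77, and CRTC1 (-0.07), also in that list, is a coactivator of CREB and not a target. For T-cell receptor and calcium output the 12 measured genes had a median of -0.036 (SD 0.12, camera adjusted p = 0.971). The rule set in advance put a route aside if its median lay under 0.1 or its list did not pass camera at 0.05. All 3 medians lay under 0.1, so by that rule all 3 routes would have been set aside. The demands on scatter and on the called genes, set after the values were seen, replaced that reading. The median of the T-cell receptor and calcium genes lay 0.136 below the bound of 0.1 set in advance, more than their SD. These 12 genes as a set did not rise, but they were dimmer than the median gene (median of their mean log2 values 6.59 against 7.26). A list drawn up without higher genes already seen cannot decide on the route. All 3 lists leave out higher genes already seen, among them CD69, IL2, DUSP4, DUSP6 (0.98), EGR1 (1.60) and SIK1 (1.33). With the 6 called higher genes put back, medians were 0.074 (SD 1.13) for T-cell receptor and calcium genes, 0.234 (SD 1.14) for ERK and 1.94 (SD 1.28) for CREB. These medians depend on the same 6 genes added to each list, so by them no route is excluded or favoured as their source. Without the 6, the ERK and CREB genes lay below 0.1 by less than their SD, so the 3 routes cannot be told apart by these lists. None is favoured by its further genes.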
